A study of Mus musculus with 6 samples.

How the data were processed

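Total RNA from 6 samples of EB3, a mouse embryonic stem (ES) cell line, was profiled for microRNAs (miRNAs, short non-coding RNAs that repress target transcripts) on single-colour Agilent mouse miRNA arrays, with 1 array per sample and all arrays on 1 slide. The titles and source names given by the submitters place 3 samples in a control group without Activin and 3 in a group differentiated with Activin. Cy3 label had been attached to 100 ng of total RNA per sample, per the labels. The sources used here do not say whether the 3 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. All choices of test, filter, miRNA list and named miRNA were fixed before the data were examined, except where a choice is said to have been made afterwards.

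The values of each deposited scanner file are spot intensities on a linear scale, written by Agilent Feature Extraction, version 10.7.3.1 per the file headers. Per the submitters' processing notes the version was 10.1.1, and the 2 statements were not reconciled here. Per the file headers the software had subtracted background and flagged outlying spots, and the headers name no scaling between arrays. The deposited series table held the same background-subtracted spot intensities, equal to the scanner values on every array. Its column medians over all rows were 1.52, 1.77 and 1.29 intensity units for control and 1.84, -0.0489 and 1.24 for Activin. Its scale is thus linear, without centring and in the direction of 1 colour, and none of the 3 stays unknown. The flags that mark spots well above background, outliers and detected miRNAs are the authors' deposited software calls. Each array held 13715 spots, of which 13000 belonged to 1857 probes for 650 miRNAs (611 from mouse and 39 from mouse viruses), with 20 spots per miRNA.

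Background-subtracted intensities of spots without an outlier flag were averaged on the linear scale over the spots of a probe and then over the probes of a miRNA. Each array was divided by the 75th percentile over the 59 probes detected on all 6 arrays. The scaled signal was floored at 0.0326 (log2 of -4.94), the median over arrays of the percentile 1 of detected miRNAs, and then converted to log2. A probe counted as detected on an array where more than 0.5 of its spots were well above background, and a miRNA where at least 1 of its probes was. The test covered the 79 mouse miRNAs detected on all 3 arrays of at least 1 group. Of their 474 values, 1 lay at the floor. Among tested miRNAs, 6 had 2 or more probes detected on all 6 arrays, and in none of these did the probes differ in sign. Different probes and miRNAs bind with different strength, so no level of a miRNA is set against that of another.

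Activin was compared with control by a linear model with moderated variances (limma 3.58.1 in R 4.3.3, lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 79 tested miRNAs and a threshold of 0.05 on adjusted p. Intervals are at the 95% level. The moderation pooled the variances almost fully, with 194 prior degrees of freedom, so SEs of the 79 miRNAs lay between 0.293 and 0.310. SEs, intervals and p-values thus reflect a shared spread more than that of each miRNA. miRNA lists for 18 families, clusters and cell types were tested with camera at a preset correlation of 0.01 where at least 3 members were tested, with adjustment over the 7 lists that reached that number. A shift of a list is the mean log2 fold change of its members minus that of the other tested miRNAs. The test was repeated with a correlation estimated from the data and with fry, which asks whether the members of a list move one way without comparing them with other miRNAs. Numbers of detected miRNAs and per-array list values were compared by exact permutation tests, two-sided, which cannot give a p below 0.1 with 3 arrays against 3. The named miRNAs follow a rule. It takes the 12 largest rises and the 12 largest falls among miRNAs past the threshold whose groups did not overlap, which gave none, up to 3 tested members of each list by size of change, and, with fewer than 5 past the threshold, the 5 with the smallest p. This named 27 miRNAs, and others are said to have been chosen after their values were seen.

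A miRNA that is not well above background on any array of a group has only a bound there. The fold is then given as at least the ratio of the mean of the brighter group to the mean, over arrays of the dimmer group, of the highest of the lowest detected signal, the floor and the miRNA's own signal. miRNA names are those of the array design, without version tags. They were matched to genes in a RefSeq table of assembly GRCm38.p6, which 551 of the 611 mouse miRNAs did. The file headers name mm9 for the design, so the table was used for symbols and no coordinates are given. Of the 27 named miRNAs, 24 matched, and miR-720, miR-92a and miR-21 keep the name of the array.

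The test was checked on simulated data for activin against control with 3 arrays each and the 79 tested miRNAs, of which 10 were changed. It recovered 54% of 2-fold changes, 93.6% of 3-fold changes and 4.7% of 1.5-fold changes. False calls made up 4.93%, 4.49% and 24.2% of the calls in these 3 cases. A list of 5 members with a simulated shift of -0.65 passed the threshold in 90% of simulations, and an unshifted one in 0%. The noise was drawn independently for each miRNA, with no deviation shared by the miRNAs of an array. None of these rates therefore holds where miRNAs move together, within a list or across an array. In the data the estimated correlation was 0.324 within the miR-290 cluster and 0.838 within the Dlk1-Dio3 list. The number of arrays limits the precision of the comparison.

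Alternatives fixed beforehand covered the scaling (the 75th percentile over all mouse miRNA probes, quantile, none, median centring, spike-in probes), the background correction, the source of the values, the summary over probes, the floor, the filter on dim miRNAs, the variance model, the thresholds, the replicate number as a block, the row of the slide and leaving out each array. The first slide row holds the 3 control arrays and, of the activin arrays, only activin 1, so only effect sizes are given for it. The background alternative, normexp with an offset of 50, was to use mean spot signals. It was run on median spot signals with median local backgrounds, since the files used here have no column of mean signals. Alternatives chosen after seeing the data were the slide column as a block, the omission of the 2 dimmest arrays, the omission of either or both of them on the same 79 miRNAs, array weights, the spike-in level of each array as a covariate, the estimated correlation of lists under every alternative, and a filter asking for detection on 2 arrays of a group. With slide column as a block, control 3 and activin 1 stand alone in columns 3 and 4 and add nothing to the contrast. It then rests on 2 pairs of arrays, too few to estimate a correlation within a list. Both pairs set an activin array in slide row 2 against a control array in row 1, so the block does not separate group from row. Figures were drawn with matplotlib 3.10.9.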

Results

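miRNA levels were measured in EB3 cells, a mouse ES cell line, to compare 3 control samples with 3 samples differentiated with Activin. Activin is a ligand of the TGF-beta family used to steer ES cells towards mesendodermal and endodermal fates. Per the labels it was given at 10 ng/ml through 3 days of embryoid body culture and 15 days of adherent culture on gelatin, and cells were harvested on day 18. The culture text is identical for all 6 samples, so the sources used here do not state whether control cells were undifferentiated or had been differentiated without Activin. The control arrays detected 80, 119 and 111 mouse miRNAs and the activin arrays 119, 54 and 110. The means were 103 ± 20.6 and 94.3 ± 35.2 (SD, n = 3 each, exact permutation p = 0.7). Without activin 2 the difference of -9.0 miRNAs turned to 11.2. Of the 611 mouse miRNAs on the array, 53 were detected on all 6 arrays, 130 on at least 1 and 481 on none.

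Control 1 and activin 2 were the dimmest arrays. The 75th percentile of detected probes was 249, 616 and 427 intensity units on the control arrays and 570, 177 and 554 on the activin arrays. On the same 2 arrays the software's metric of spread between replicate spots was out of range, at a median coefficient of variation of 17.6% and 15.8% against 6.88% to 9.59% on the others. The metric for labelling spike-ins was out of range on all 6 arrays, and that for hybridisation spike-ins was in range on all 6. No miRNA spot was saturated. Control 1 and activin 2 shared column 1 of the slide, and control 2 and activin 3 shared column 2. The 3 control arrays and activin 1 lay in row 1, and activin 2 and activin 3 in row 2. Across the 79 tested miRNAs, log2 values correlated at r = 0.949 ± 0.023 within groups (SD over 6 pairs of arrays) and at 0.930 ± 0.032 between groups (9 pairs), so the distance between groups was within the spread of array pairs. Control 3 correlated at 0.975 and 0.973 with activin 1 and activin 3 and at 0.955 with control 2. miRNAs are not independent replicates in these correlations.

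**Figure D1:**
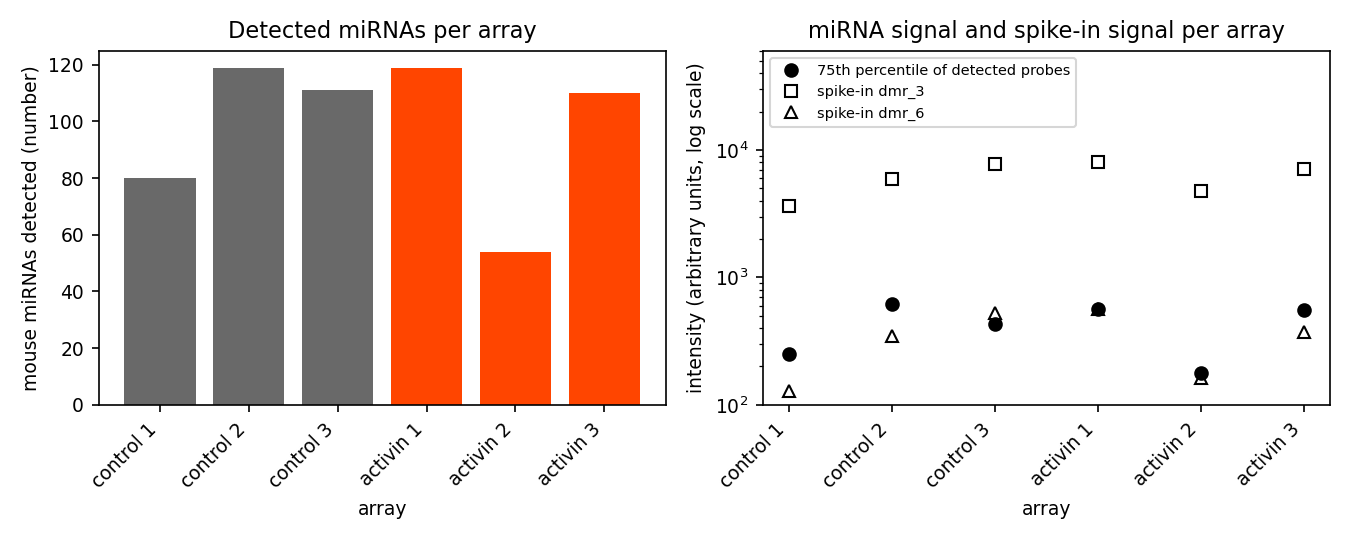
Left, the number of mouse miRNAs detected on each array, with control arrays in grey and activin arrays in orange. Right, on a log scale of intensity in arbitrary units, the 75th percentile of probes detected on all 6 arrays and the mean of 2 spike-in controls on each array. Control 1 and activin 2 detected 80 and 54 miRNAs, fewer than the 110 to 119 on the other 4 arrays.

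Activin-treated and control cells differed past the threshold in 1 miRNA. miR-302c (Mir302c), a member of a cluster with miR-367 that is found in ES cells and epiblast, was higher with Activin, with a log2 fold change of 1.23 (SE 0.30, 95% interval 0.63 to 1.82, limma adjusted p = 0.00597), a 2.34-fold change. Its mean log2 signal was -4.08 ± 0.89 in control, where it was detected on 2 of 3 arrays, and -2.85 ± 0.33 with Activin (SD, n = 3 each), detected on all 3. The groups touched, since control 3 at -3.10 lay above activin 2 at -3.23. The SE, interval and p rest on the variance pooled over all 79 miRNAs rather than on the SD of 0.89 of miR-302c in control. miR-720, a sequence later reclassified as a tRNA fragment, had the next smallest p, with a log2 fold change of -0.85 (SE 0.29, adjusted p = 0.17) and groups that did not overlap. No miRNA fell past the threshold, and miR-302c was the only call among 79 miRNAs tested with limma, 9 of which had an unadjusted p under 0.05 (4 higher and 5 lower with Activin). Only miR-302c entered the test through the activin arrays alone, as the other 78 miRNAs were detected on all 3 control arrays. All 3 activin arrays detected 54 miRNAs, so the filter left little room for other miRNAs gained with Activin.

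The call of miR-302c was lost on leaving out any 1 array other than control 3, with adjusted p from 0.127 to 0.698 and log2 fold changes of 0.85 without control 1 and 1.09 to 1.25 without each of the others. It was also lost with the 5 other scalings, with adjusted p of at least 0.268 and log2 fold changes of 0.80 to 1.12. The log2 fold change was 0.67 with the mean of log2 over probes (adjusted p = 0.351) and 0.80 with the floor at 2 times (adjusted p = 0.440), while the brightest probe gave 1.29 (adjusted p = 0.0609) and no filter 1.23 (adjusted p = 0.428). With normexp background its log2 fold change was -0.21. With slide column as a block the adjusted p = 0.00202, and activin exceeded control by 1.61 in column 1 and 1.56 in column 2. That fit rests on these 2 pairs of arrays. In both, the activin array lay in row 2 of the slide and the control array in row 1. The fit therefore does not separate the group from the slide row.

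The median log2 fold change of the 79 miRNAs was 0.17, with 50 above 0 and 29 below. It was -0.02 with the 75th percentile of all probes, 0.04 with quantile scaling, 0.09 without scaling, 0.01 with median centring, -0.11 with spike-in scaling and -0.31 with normexp. Relative to that median, miR-302c stood at 1.06 and at 0.10 to 1.08 under these 6 alternatives. miR-720 stood at -1.01, and at -1.03 to -0.36 under them. Groups did not overlap for 14 miRNAs, 9 higher and 5 lower, where chance gives 10% of 79. The interval bounds lay a median of 0.58 on the log2 scale from the estimate, and the intervals of 56 miRNAs excluded a 2-fold change in either direction. These intervals rest on the pooled variance and on the main scaling alone. They therefore do not establish that these miRNAs stayed within 2-fold.

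The miR-290 cluster, whose miRNAs are abundant in mouse ES cells, stood lower with Activin as a group, while none of its members passed the threshold alone. All 5 tested members of the 14 on the array were below the median of all tested miRNAs under the main and 5 alternative scalings, and 4 were with normexp, where miR-293 stood 0.05 above it. The list shifted by -0.65 relative to the other miRNAs (camera adjusted p = 0.00117 with the preset correlation). With an estimated correlation the adjusted p = 0.374, and it stayed at 0.0830 or above under every alternative. miR-292-3p (Mir292) had a log2 fold change of -0.74 (SE 0.30, adjusted p = 0.216), miR-291a-3p (Mir291a) one of -0.67 (SE 0.29, adjusted p = 0.263) with groups that did not overlap, and miR-293 (Mir293) one of -0.43 (SE 0.30, adjusted p = 0.529). Adjusted over the list alone, 0 members passed, with a lowest p of 0.0582 after limma adjustment. The list mean relative to other miRNAs was 2.79, 1.67 and 1.99 on the control arrays and 1.54, 1.44 and 1.51 on the activin arrays (exact permutation p = 0.1, the smallest possible). Without control 1, a dim array, the shift was -0.35 (adjusted p = 0.0735, 107 miRNAs tested) and, on the same 79 miRNAs, -0.33 (adjusted p = 0.0780), and with normexp it was -0.16 (adjusted p = 0.192). With slide column as a block it was -0.75 (adjusted p = 0.00168, and 0.881 with an estimated correlation), from -1.35 in column 1 and -0.15 in column 2. That fit rests on 2 pairs of arrays, which cannot estimate a correlation, so neither p decides the question.

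miRNAs of the imprinted Dlk1-Dio3 region stood higher with Activin as a group, again with no single member past the threshold. Of 63 such miRNAs on the array 20 were detected on at least 1 array and 8 were tested. All 8 were above the median of all tested miRNAs under the main and 5 alternative scalings, and 6 were with normexp. The list shifted by 0.42 relative to the other miRNAs (camera adjusted p = 0.012 with the preset correlation). With an estimated correlation the adjusted p = 0.709, and it stayed at 0.354 or above under every alternative. miR-431 (Mir431) had a log2 fold change of 0.72 (SE 0.30, adjusted p = 0.216) with groups that did not overlap, miR-370 (Mir370) one of 0.64 (SE 0.30, adjusted p = 0.316) and miR-410 (Mir410) one of 0.57 (SE 0.30, adjusted p = 0.414). Adjusted over the list alone, 0 members passed, with a lowest p of 0.128 after limma adjustment. Without control 1, a dim array, the same 8 members among the same 79 miRNAs shifted by 0.38 (adjusted p = 0.0165, and 0.509 with an estimated correlation). The filter then let in 107 miRNAs, of which 16 members shifted by 0.21 (adjusted p = 0.0735). Without control 2 the shift of the 8 was 0.32 (adjusted p = 0.142). With slide column as a block the shift was 0.57 (adjusted p = 0.00266, and 0.881 with an estimated correlation), from 0.46 in column 1 and 0.68 in column 2. This fit, too, rests on 2 pairs of arrays, which cannot estimate a correlation.

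**Figure D2:**
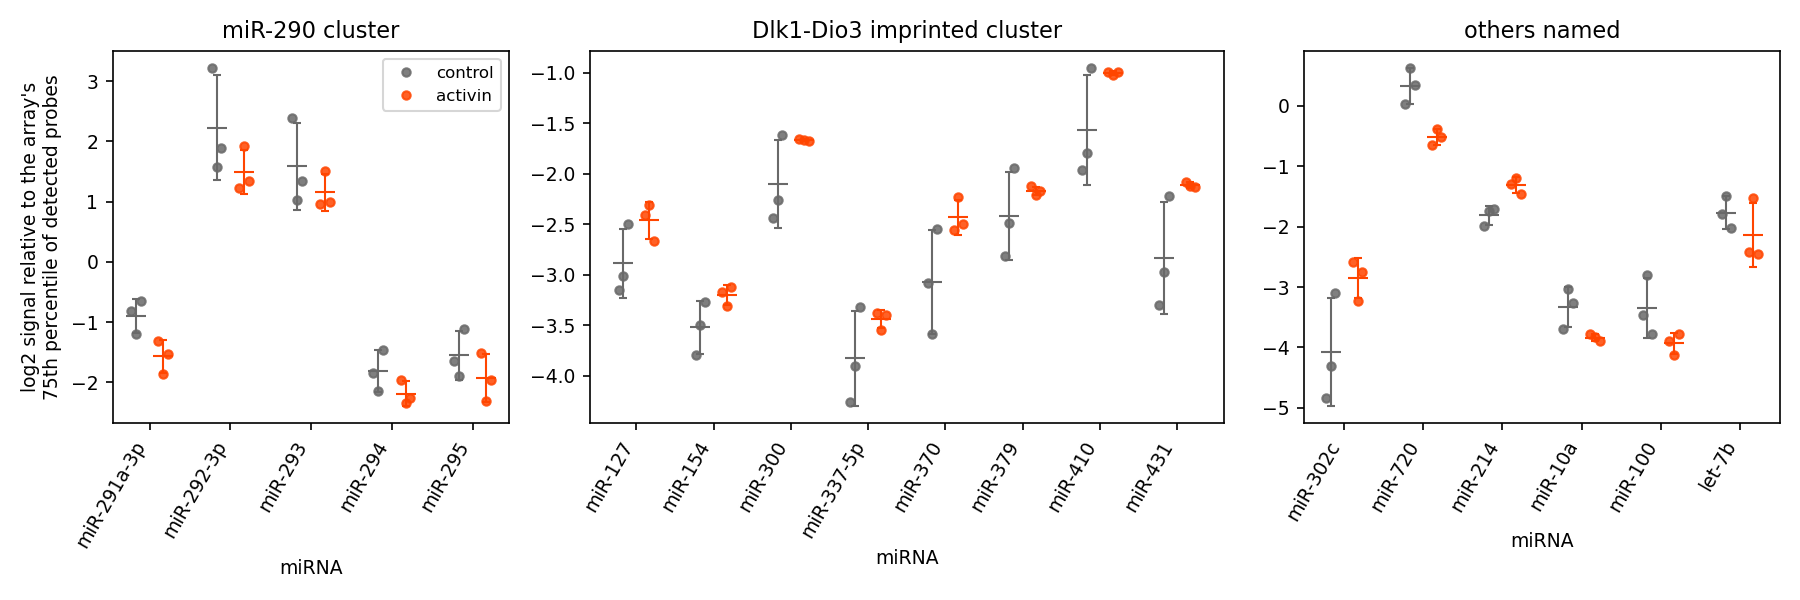
Log2 signal relative to the 75th percentile of detected probes of each array, for the tested members of the miR-290 cluster, of the Dlk1-Dio3 region and for 6 other named miRNAs. Points are arrays (control grey, activin orange), and bars give the mean and SD of 3 arrays. The 3 activin arrays of miR-291a-3p lie below and those of miR-431 above all control arrays, and for miR-302c the groups overlap at control 3.

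Of the other members of the miR-302 and miR-367 cluster, miR-302a and miR-367 were detected on 2 control and 2 activin arrays, and miR-302b and miR-302d on 0 control and 2 activin arrays. They were not tested, and miR-302b and miR-302d with Activin did not exceed the bound in control. On the 4 brighter arrays alone (2 against 2, chosen after seeing the data), no single miRNA passed the threshold among 115 tested with limma, 8 having an unadjusted p under 0.05.

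The let-7 family, which builds up as ES cells differentiate, gave no call in either direction. Of 8 tested members, 7 were below 0 and 1 above, and the list shifted by -0.25 (camera adjusted p = 0.197, and 0.709 with an estimated correlation). let-7b (Mirlet7b) had a log2 fold change of -0.37 (SE 0.30, adjusted p = 0.589), let-7i one of -0.36 and let-7d one of -0.29. The shift of the let-7 list rested on which arrays were used. It was -0.54 without activin 2 (adjusted p = 9.81e-04), -0.42 without control 3 (adjusted p = 0.0322), -0.52 without both dim arrays (adjusted p = 0.00397) and -0.07 without control 2, and within slide columns it was 0.13 in column 1 and -0.82 in column 2. With an estimated correlation the let-7 list passed under none of the alternatives (adjusted p of at least 0.418). With slide column as a block the shift was -0.35 (adjusted p = 0.105).

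Hox cluster miRNAs had 4 tested members, all below the median of all tested miRNAs under the main and the 6 alternative scalings and backgrounds, and shifted by -0.30 (camera adjusted p = 0.226, and 0.709 with an estimated correlation). Their list means separated the groups, at -1.04 ± 0.02 in control and -1.34 ± 0.12 with Activin (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). miR-10a (Mir10a) had a log2 fold change of -0.51 (SE 0.29, adjusted p = 0.427), with groups that did not overlap and detection on 2 of 3 activin arrays. miR-10b was at -0.14 and miR-196a at -0.08. Without activin 2 the shift was -0.48 (adjusted p = 0.0106) and without both dim arrays -0.45 (adjusted p = 0.00397), but with an estimated correlation the adjusted p was 0.502 and 0.604. On the same 79 miRNAs both shifts were -0.36 (adjusted p = 0.0305 and 0.0937, and 0.418 and 0.567 with an estimated correlation). With slide column as a block it was -0.30 (adjusted p = 0.289), from -0.18 and -0.42 in the 2 columns.

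Mesenchymal and smooth muscle miRNAs, a list that also marks fibroblast-like cells, shifted by 0.24 (camera adjusted p = 0.239, and 0.709 with an estimated correlation). All 5 tested members were above the median of all tested miRNAs, and 4 were with quantile scaling or normexp. miR-214 (Mir214) had a log2 fold change of 0.50 (SE 0.29, adjusted p = 0.427) and miR-21 one of 0.30 (SE 0.29, adjusted p = 0.619), both with groups that did not overlap, and miR-199a-3p one of 0.34 (SE 0.30, adjusted p = 0.614). The proliferation-linked clusters of miR-17, miR-106a and miR-106b gave -0.04 over 7 members (camera adjusted p = 0.807), a shift that turned to 0.08 with quantile scaling and 0.20 with normexp, while their median log2 fold change was 0.02. Among them miR-25 was at 0.31, miR-92a at 0.24 and miR-19b at -0.15, and miR-25 was detected on 2 of 3 activin arrays. The group of miR-99, miR-100 and miR-125, whose genes lie beside let-7 genes, gave -0.15 over 4 members (camera adjusted p = 0.544) with a median of 0.03. In it miR-100 was at -0.58 (SE 0.30, adjusted p = 0.405, detected on 2 of 3 activin arrays), miR-125a-5p at 0.35 and miR-125b-5p at 0.15. No member of these lists, of let-7 or of the Hox clusters passed when adjusted over the list alone.

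**Figure D3:**
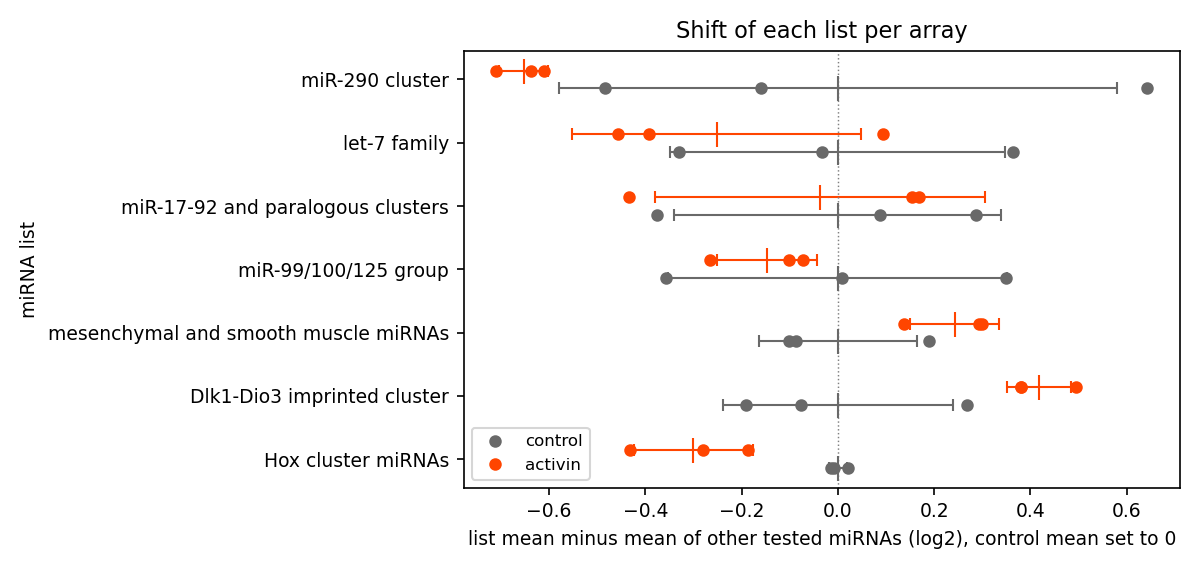
Mean log2 signal of each list minus that of the other tested miRNAs on each array, drawn so that the mean of the 3 control arrays is 0. Points are arrays (control grey, activin orange) and bars give the mean and SD of 3 arrays. The activin arrays lie apart from the control arrays for the miR-290 cluster (difference -0.65), the Dlk1-Dio3 region (0.42) and the Hox clusters (-0.30), where 3 against 3 arrays cannot give an exact p below 0.1.

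Markers of islet, liver and gut, blood, striated muscle and neural lineages were mostly not well above background in either group. Mesenchymal and smooth muscle miRNAs, by contrast, had 5 of 10 detected, 4 of them on all 6 arrays, and epithelial miRNAs had 3 of 12. Of 6 pancreatic islet miRNAs, 4 liver and gut miRNAs and 8 haematopoietic miRNAs, 0 were detected on any array. Striated muscle had 1 of 8 (miR-133b on activin 1), neural lists 2 of 10 (miR-124 on control 2, and miR-9* on 2 arrays of each group), and endothelial miR-126-3p was detected on 1 control and 2 activin arrays. The Sfmbt2 intron families had 1 of 39. Of the epithelial miRNAs, miR-200b had a log2 fold change of 0.29 (SE 0.30, adjusted p = 0.619) and miR-200c one of 0.10 (SE 0.30, adjusted p = 0.887), and both turned below 0 without the 2 dim arrays, to -0.05 and -0.32. miR-34a, of the p53-regulated miR-34 family, was at 0.16 (SE 0.29, adjusted p = 0.813), close to the median of all tested miRNAs. miR-1895 (Mir1895) was detected on all 3 control arrays and on 0 activin arrays, and was at least 1.11-fold higher in control (limma adjusted p = 0.216).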

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

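Of the tests in this part, those on array yield, on the dim arrays, on the same miRNAs without them, on slide columns and with the spike-in level as a covariate were chosen only after the results were seen. A probe for a viral miRNA, mghv-miR-M1-2-3p of murine gammaherpesvirus, stood out because viral probes have no source in these cells by design. It was detected on 1 array, control 1, by the majority of its spots and on 5 arrays by the software's own call, with mean intensities of 21.6, 22.0 and 21.5 in control and 23.5, 16.8 and 18.8 with Activin. By the majority of spots it was the 1 viral miRNA of 39 detected on any array, and no explanation of its signal was tested.

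Control 1 and activin 2 were dimmer than the other 4 arrays, with a miRNA scaling value 0.391 times theirs. Low yield of labelling or hybridisation on these arrays is a candidate explanation. The hybridisation spike-ins dmr_3 and dmr_6, detected on all 6 arrays, were also dimmer there, though their metric was in range. Their ratios differed, at 0.579 for dmr_3 and 0.325 for dmr_6, with a geometric mean of 0.433. These spike-ins do not report labelling. The labelling spike-in dmr_31a stood at 26.2 on control 1 and 24.2 on activin 2, against 59.6 to 79.8 on the others. The labelling metric was out of range on all 6 arrays, so labelling was not told apart from hybridisation. Less miRNA in these 2 samples stays open. The miRNA signal over the geometric mean of dmr_3 and dmr_6, which differed, had a ratio of 0.903 to the other arrays. Its values were, however, 0.365 on control 1 and 0.203 on activin 2, against 0.211 to 0.428 on the others. No biological explanation was tested, since the 2 arrays belong to different groups.

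The lower miR-290 cluster with Activin was weighed against the dim arrays and the slide column. Distorted signal on the dim arrays cannot be told apart as a cause, since without control 1 and activin 2 the shift was -0.39 (SE 0.11) among 115 miRNAs but -0.30 (SE 0.16) among the same 79, within its SE of the bound of -0.15. The slide column cannot be told apart either, since the smaller of the 2 shifts within columns was -0.15 and their mean of -0.75 had an SE of 0.60. The 10 splits of the 6 arrays are too few for a share under 0.05: the real shift was 0.652 in size, 1 split (the real one) gave as large a shift, and the highest other was 0.568. An effect of Activin stays open as a hypothesis.

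The higher Dlk1-Dio3 miRNAs with Activin were weighed in the same way. The slide column as the whole cause is argued against by the shifts within columns, the smaller being 0.46 and their mean 0.57 (SE 0.11, from 2 pairs of arrays). Each pair set an activin array in row 2 of the slide against a control array in row 1. The slide row therefore cannot be told apart from the group within these pairs. The dim arrays cannot be told apart as a cause, since without them the shift was 0.40 (SE 0.24) for the same 8 members and 0.30 (SE 0.25) for the 18 members then tested, the latter within its SE of the bound of 0.15. On all 6 arrays the shift was 0.42 for the 8 members and 0.27 for the 18. The members added to the 8 were not detected on either dim array. The 18 members therefore cannot show what leaving out these arrays does. Again 10 splits are too few for a share under 0.05: the real shift was 0.418, 1 split (the real one) gave as large a shift, and the highest other was 0.343. An effect of Activin stays open as a hypothesis.

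For the count of miRNAs past the threshold, 2 of the 10 splits (the real one among them) gave at least as many as the real 1. Here, too, 10 splits are too few for a share under 0.05. The highest other split called 16 miRNAs, with more miRNAs tested than the real split, which points to a structure of the samples or arrays other than their group. It set control 1, control 2 and activin 2 against control 3, activin 1 and activin 3. The first 3 arrays had spike-in levels of 682, 1440 and 874 intensity units, and the other 3 had 2023, 2142 and 1614. With the spike-in level as a covariate, limma called 5 miRNAs between activin and control (miR-302c higher, and miR-720, miR-714, miR-291a-3p and miR-1895 lower), the miR-290 shift was -0.59 (adjusted p = 0.00229) and the Dlk1-Dio3 shift 0.40 (adjusted p = 0.0119), but neither list passed the threshold with an estimated correlation.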

How the results depend on the processing

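The tests with slide column as a block, without the 2 dim arrays, on the same 79 miRNAs without dim arrays, with array weights, with the spike-in level as a covariate, with an estimated correlation under each setting and with detection on 2 arrays of a group were chosen only after the results were seen. The count of 1 miRNA past the threshold held with the series table, with the floor at 0.5 times, with trend and robust variances, with slide column as a block, with a log2 fold change of at least 1 and with adjusted p under 0.01. It was 0 with each other scaling, with normexp, with the software's total gene signal, the brightest probe or the mean of log2 over probes, with the floor at 2 times, with no filter (611 miRNAs tested), with detection on all 6 arrays (53 tested, without miR-302c), without the 2 dim arrays and with detection on 2 arrays of a group (115 tested). It was 5 with array weights (miR-302c, miR-720, miR-370, miR-100 and miR-431) and 5 with the spike-in covariate, and 0 to 1 on leaving out each array. Wider or narrower filters changed how many miRNAs were tested and the set over which variances were pooled. With no filter and with detection on 2 arrays of a group, miR-302c kept its log2 fold change of 1.23, at limma adjusted p of 0.428 and 0.446. The cause of the changed counts was not tested. The first slide row has activin 1 as its only activin array, so no count is given there, and miR-302c was at 1.28. Low signal over background limits miR-302c in particular, as control 1, at -4.83, lies near the floor.

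The replicate number as a block also gave 1 call (miR-302c, adjusted p = 0.0365). The block changed no other call. That shared numbers do not by themselves pair the samples was fixed beforehand. Deviations from the group means correlated at -0.64, -0.09 and 0.34 between arrays with the same number. Between the dim arrays, control 1 and activin 2, the value was 0.55, so these correlations do not decide on pairing.

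With an estimated correlation no list passed the threshold under any setting, so the calls of lists named next rest on the preset correlation. In the main comparison the shifts of -0.65 for the miR-290 cluster and 0.42 for Dlk1-Dio3 had adjusted p of 0.374 and 0.709 with an estimated correlation. The lowest such adjusted p over all settings was 0.0830 for the miR-290 cluster, 0.354 for Dlk1-Dio3, 0.418 for let-7 and 0.317 for the Hox clusters. With fry, which tests the members' own mean log2 fold change, adjusted p was 0.326 for the miR-290 cluster (mean -0.52) and 0.326 for Dlk1-Dio3 (mean 0.47). The miR-290 shift stayed below 0 under all alternatives and lost its call with normexp (-0.16), with array weights (-0.37), without control 1 (-0.35, adjusted p = 0.0735) and without both dim arrays on the same 79 miRNAs (-0.30, adjusted p = 0.0980), and ran from -0.89 to -0.35 on leaving out each array. The Dlk1-Dio3 shift stayed above 0 and lost its call with normexp (0.11), no filter (0.097), and detection on 2 arrays (0.27, 18 members). It also lost its call without control 1 (0.21, adjusted p = 0.0735, 16 members) and without control 2 (0.32, adjusted p = 0.142), with 0.21 to 0.55 on leaving out each array. Leaving out control 1 or activin 2 let more miRNAs through the filter, and on the same 8 members the shift was 0.38 and 0.44. The let-7 shift stayed below 0 and passed the threshold with median centring (-0.27), no filter (-0.071), without control 3 (-0.42) and without activin 2 (-0.54). It also passed without the dim arrays (-0.52) and with array weights (-0.52), these 2 having adjusted p of 0.683 and 0.536 with an estimated correlation. The let-7 shift ran from -0.54 to -0.070 on leaving out each array, and was -0.53 in the first row, where activin 1 is the only activin array. The Hox shift stayed below 0 and passed with quantile scaling (-0.39), no filter (-0.10), without activin 2 (-0.48) and without the dim arrays (-0.45, adjusted p = 0.604 with an estimated correlation). The Hox shift ran from -0.48 to -0.23 on leaving out each array, and was -0.42 in the first row. The shift of the miR-17 and related clusters turned positive with quantile scaling (0.081), normexp (0.20), total gene signal (0.016), no filter (0.029), the first row alone (0.15), slide column as a block (0.0036) and array weights (0.0096), and ran from -0.15 to 0.14 on leaving out each array. The group of miR-99, miR-100 and miR-125 turned to 0.020 with detection on all 6 arrays, and ran from -0.32 to 0.028. The mesenchymal shift kept its direction and stayed short of the threshold throughout. The difference in detected miRNAs ran from -21.3 to 11.2 on leaving out each array.

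The scalings and normexp moved the median log2 fold change of all tested miRNAs from 0.17 to as low as -0.31, so signs were also read relative to that median. Read so, miR-293 (to 0.05), miR-19b (to 0.15) and miR-200b (to -0.18) changed sign with normexp alone, and miR-125b-5p (from -0.01 to as high as 0.11) and miR-34a (from -0.01 to as high as 0.23) with quantile scaling and normexp. Apart from these 5 miRNAs, the changes of sign with a scaling or normexp given next were changes against 0 alone, where the median itself lay at -0.11 with spike-in scaling and at -0.31 with normexp. With normexp, miR-302c went to -0.21, miR-431 to -0.037, miR-370 to -0.20, miR-25 to -0.19, miR-125a-5p to -0.26, miR-125b-5p to -0.20, miR-200b to -0.48, miR-200c to -0.46 and miR-34a to -0.071. With spike-in scaling, miR-92a went to -0.036, miR-125b-5p to -0.13, miR-200c to -0.18 and miR-34a to -0.12. With the 75th percentile of all probes, miR-125b-5p went to -0.033, miR-200c to -0.085 and miR-34a to -0.026, and with median centring miR-125b-5p to -0.0066 and miR-200c to -0.058. miR-200c was at -0.11 with quantile scaling, -0.027 with total gene signal, -0.34 in the first row, -0.32 without the dim arrays and -0.14 with array weights. miR-200b was at -0.048 without the dim arrays, miR-19b at 0.094 and miR-34a at -0.17 in the first row, and miR-196a at 0.035 with the mean of log2 over probes. With slide column as a block, miR-10b was at 0.027, miR-196a at 0.038 and miR-19b at 0.0060. On leaving out each array, ranges that crossed 0 were -0.42 to 0.11 for miR-10b, -0.093 to 0.34 for miR-125b-5p, -0.39 to 0.067 for miR-196a, -0.64 to 0.24 for miR-19b, -0.068 to 0.52 for miR-200b, -0.53 to 0.45 for miR-200c, -0.21 to 0.72 for miR-25 and -0.053 to 0.23 for miR-34a.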

Other observations

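The miRNAs of this paragraph were chosen after their values were seen, from those with groups that did not overlap or with an unadjusted p under 0.05, and none passed the threshold after limma adjustment. Higher with Activin were miR-322, clustered with miR-503, with a log2 fold change of 0.61 (SE 0.31, adjusted p = 0.405), miR-652 with 0.52 (SE 0.29, adjusted p = 0.427) and miR-27a, clustered with miR-23a and miR-24, with 0.51 (SE 0.30, adjusted p = 0.427). miR-322 had overlapping groups, with SDs of 1.11 in control and 0.51 with Activin (n = 3 each). Also higher with groups apart were miR-151-5p at 0.49, miR-324-5p at 0.48 and miR-361 at 0.32. Lower with Activin was miR-714, at -0.71 (SE 0.30, adjusted p = 0.216), with groups apart and detection on 2 of 3 activin arrays.

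On the 4 brighter arrays, a choice made after seeing the data, 2 further members of the miR-302 and miR-367 cluster were detected on every array. miR-302a had a log2 fold change of 0.84 (SE 0.27) and miR-367 one of 0.10 (SE 0.22), beside 1.06 (SE 0.33) for miR-302c. Their limma adjusted p ranged from 0.433 to 0.851, with 2 arrays in each group.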
